A study of Mus musculus with 15 samples.

How the data were processed

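Gene expression was measured on Affymetrix arrays in 15 mouse samples, 5 of wild type C57BL/6J liver, 5 of liver around a tumour in Mat1a-deficient 129 SvJ mice and 5 of tumours of such mice. Per the labels, tissue was taken by laparotomy and flash frozen, RNA was purified on columns and checked for integrity, and biotin-labelled cRNA was hybridized. The deposited values are log2 signals that the authors made by RMA, which corrects background, normalizes quantiles and summarizes probe sets over the arrays; no version or settings are stated. The values were used as deposited. The number of arrays limits the precision.

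Of 22690 probe sets, 64 were controls, 20380 carried 1 gene symbol and 691 carried several. The symbols came from the platform's annotation, in which 20364 gene identifiers were found in a RefSeq table and 0 symbols were changed by it. Each of 12393 genes was represented by its probe set with the highest mean over all arrays, a choice that mattered for the 4956 genes with more than 1 probe set. The 2246 probe sets with several symbols or none were tested apart.

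All 3 groups were fitted together with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, 12 residual degrees of freedom), and p-values were adjusted by Benjamini-Hochberg over all genes. A gene was called at an adjusted p under 0.05, and 2-fold changes needed an absolute log2 change of at least 1. Comparisons were tumour against peritumour, peritumour against wild type and tumour against wild type. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

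Before the data were examined, 34 gene lists with 1008 memberships were fixed from general knowledge of liver and liver tumours, of which 873 were measured. They were methionine and one-carbon metabolism, glutathione and antioxidant defence, bile acids, cytochromes P450 and conjugation, urea cycle and amino acid catabolism, glycolysis, gluconeogenesis and glycogen, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, the respiratory chain, and secretory proteins with hepatocyte identity. Further lists were fetal liver and tumour markers, cell division, DNA replication, beta-catenin targets, ERK targets, p53 targets, the unfolded protein and amino acid stress response, the acute phase response and the interferon response. Markers of other cells covered matrix and stellate cells, macrophages and Kupffer cells, T and NK cells, B cells, neutrophils, cholangiocytes and progenitors, endothelium, pancreatic acini, and adipocytes with mesothelium and blood. The last were male-biased genes, female-biased genes, sex chromosome genes, and genes with loss-of-function alleles that differ between the strains. The 32 lists with at least 5 measured members were tested with camera of limma at a preset correlation of 0.01, and again with a correlation estimated for each list. A list shares some members with others, so lists are not independent.

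The genes named in the text were chosen by a rule fixed before the data were examined. For each of the first 2 comparisons it took up to 10 called genes each way by size of change whose groups did not overlap, and for tumour against wild type 5 each way. From every list it took up to 4 members with the smallest p, and it added Mat1a, Mat2a, Nnt and the sex chromosome genes, of which Mat2a had no probe set under its symbol in the annotation used. Ly6d in tumour against peritumour was named after its blocked value was seen.

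The samples of each group are numbered 1 to 5, and no label says that a number marks an animal. From the data, deviations from the group mean of same-numbered peritumour and tumour arrays correlated at 0.353, 0.673, 0.256, 0.293 and 0.104, each above 0.1. The same number was the best match for 4 tumour and 4 peritumour arrays, and the numbers were taken to pair these groups. The value of 0.1 alone does not part paired from unpaired arrays. Same-numbered wild type and peritumour arrays reached 0.218, and wild type and tumour arrays 0.115. The pairing thus remains an assumption, weakest for number 5. For the genes named as changed the report gives which passed with the number as a block and the range of the others. The wild type arrays are not paired with the others, so in their comparisons the block is an alternative only. The fit with the block held only the 2 groups compared, which also leaves fewer residual degrees of freedom than the main fit. The main values carry no block, as fixed before the data were examined.

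On simulated data with 200 changed genes, limma recovered 32%, 66%, 94% and 96% of changes of 0.5, 1, 2 and 3 log2 units in the design of tumour against peritumour. For peritumour against wild type the shares were 40%, 72%, 88% and 100%, and for tumour against wild type 30%, 70%, 90% and 100%. The simulated noise was independent between arrays and genes, with no outlying arrays and no shared deviation of same-numbered arrays. These shares therefore need not hold for the real arrays.

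Alternatives fixed before the data were examined were quantile normalization, centring on array medians, the mean of all probe sets, no shared-probe sets (12106 genes), the 40% dimmest genes left out (7436 genes remained, above a mean of 5.35), a trended robust variance, only the 2 groups compared, array weights, the replicate block, an estimated correlation, split peritumour arrays, and each array left out in turn. Leaving out peritumour 2 with tumour 2, or these with wild type 4 and tumour 5, was added after the array correlations were seen. Group labels were also redrawn 100 times out of 126 possible splits. The genes of the signature in the series title are not given in the sources used and were not analysed here.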

Results

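Livers of mice lacking Mat1a, the gene of the methionine adenosyltransferase that makes S-adenosylmethionine in adult liver, were compared with livers of wild type mice on Affymetrix expression arrays. The 15 arrays fell into 3 groups of 5, namely wild type liver, liver lying around a tumour in Mat1a-deficient mice (peritumour) and the tumour tissue of Mat1a-deficient mice. The wild type mice were C57BL/6J and the deficient mice 129 SvJ, so genotype and strain differ together in both comparisons against wild type. Values are log2 signals normalized by robust multi-array averaging (RMA), with array medians between 5.47 and 5.68, and 12393 genes were tested. Nothing in the labels says that the 5 samples of a group came from separate animals, so p-values measure the spread between these samples, and the number of arrays limits the precision.

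Mat1a was measured by 1 probe set, and where its probes lie relative to the disrupted part of the gene is not given in the sources used here. On the wild type arrays 1 to 5 it read 12.30, 12.25, 12.67, 12.72 and 12.68. The peritumour arrays 1 to 5 gave 8.84, 11.44, 9.02, 8.99 and 9.29, and the tumour arrays 1 to 5 gave 8.72, 10.47, 8.63, 8.33 and 10.50. All 10 deficient arrays lay below all wild type arrays, with peritumour 2 closest to them. Mat2a, the related enzyme gene of other tissues, was not analysed here, as no probe set carried its symbol in the annotation used.

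Correlations between arrays ran from 0.904 to 0.992, and no pair held identical values. Within each group, the mean correlation with the own group was lowest for tumour 2 (0.929) and tumour 5 (0.930), for peritumour 2 (0.939) and for wild type 4 (0.964). It was 0.950 to 0.960 for the other tumours, 0.971 to 0.977 for the other peritumour arrays and 0.981 to 0.984 for the other wild type arrays. Peritumour 2 and tumour 2 correlated best with each other (0.967), and wild type 4 correlated best with peritumour 4 (0.981). The signal of pyruvate carboxylase at its 3-prime end exceeded that at its 5-prime end by 2.31 to 3.45 log2 units on wild type arrays, 2.04 to 2.61 on peritumour arrays and 1.86 to 2.16 on tumour arrays.

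**Figure D1:**
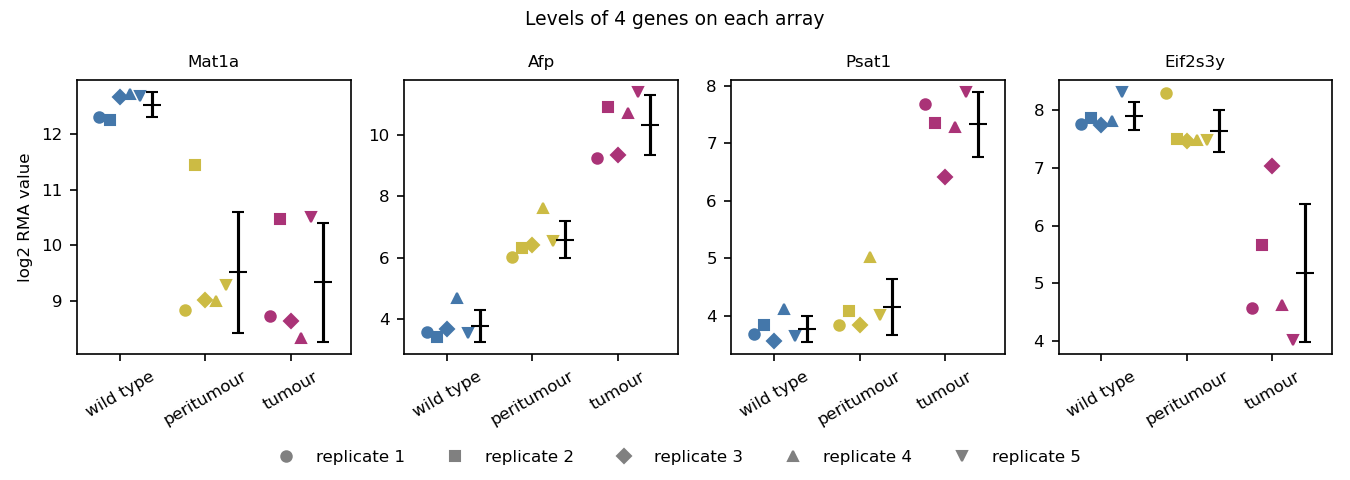
Log2 RMA values of Mat1a, Afp, Psat1 and Eif2s3y on each of the 15 arrays, with 1 panel per gene and its own vertical axis; symbols mark the replicate number, and the black dash and bar beside each group give the mean and SD of 5 arrays. Peritumour 2 reads 11.44 for Mat1a against 8.84 to 9.29 on the other peritumour arrays, and Afp rises from a mean of 3.78 in wild type liver to 6.59 in peritumour liver and 10.32 in tumours.

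The first comparison, tumour against peritumour liver of the same genotype and strain, addresses what distinguishes the tumours from the tissue around them. Afp, the fetal serum protein alpha-fetoprotein, rose by 3.73 ± 0.42 log2 units (SE, n = 5 and 5 arrays), and Psat1, an enzyme of serine synthesis, rose by 3.16 ± 0.27. The stress-induced regulator Nupr1 rose by 2.83 ± 0.39, the stem cell surface protein gene Prom1 by 2.80 ± 0.46 and the carbonyl reductase gene Cbr3 by 2.67 ± 0.37. Among the genes that fell were the Y-linked gene Eif2s3y (-2.47 ± 0.43), the chemokine gene Cxcl12 (-1.58 ± 0.19) and the betaine transporter gene Slc6a12 (-1.23 ± 0.22). Each of these 8 genes had all 5 tumour values on one side of all 5 peritumour values, which the naming rule required, so it adds no support. The peritumour means of Psat1 (4.16) and Prom1 (4.56), and the tumour mean of Pcsk5 (4.38) named below, lay under 4.64, the highest Xist value on any array, and are not shown to be above background, so the size of these changes is uncertain.

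In limma with Benjamini-Hochberg adjustment 26 genes changed, 16 higher and 10 lower, and 16 of them changed at least 2-fold, 11 higher and 5 lower. Adjusted p was 0.000103 for Psat1, 0.00211 for Afp, 0.00393 for Cxcl12, 0.00749 for Nupr1 and Cbr3, 0.0318 for Prom1, 0.0346 for Eif2s3y and 0.0374 for Slc6a12. Among the other genes that rose were Emcn (1.56), Comtd1 (1.51), Nqo1 (1.19), Jpt1 (1.16) and Cbr1 (1.15). Others that fell were Zeb2 (-1.11), the coagulation factor gene F7 (-0.94), the folate enzyme gene Aldh1l1 (-0.93), the glutamine transporter gene Slc38a3 (-0.92), Pcsk5 (-0.88), the pyrimidine-degrading enzyme gene Dpyd (-0.72) and the endothelial gene Ehd3. The groups of 288 genes (2.3%) did not overlap, where chance gives 0.79%, and 25 of the 26 changed genes were among them. The exception was Bex1 (4.42 ± 0.78, adjusted p = 0.0349), which read 7.60 on peritumour 2 against 3.27 to 3.93, near background, on the other peritumour arrays.

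Same-numbered peritumour and tumour arrays deviated together, and with the number as a block 6 genes passed. These were Afp and Psat1 and Nupr1 (blocked adjusted p = 0.0433 each), Bex1 and Slc6a12 (0.0472 each), and Ly6d (2.56, blocked adjusted p = 0.0472 against 0.129 without the block). The blocked adjusted p of the other genes named above as changed lay between 0.0912 for Prom1 and 0.181 for Emcn and Ehd3. The blocked fit held only the 2 groups compared, and these 2 groups without the block gave 4 genes. Fewer calls with the block than in the main fit are therefore not read as an effect of the pairs. Leaving out 1 array moved the 26 genes to 6, 60, 12, 9 and 6 without peritumour 1 to 5 and to 13, 135, 144, 8 and 43 without tumour 1 to 5. Of the 144 without tumour 3 43.1% were higher in tumours, against 61.5% of the 26. The 16 genes changed at least 2-fold became 6, 37, 10, 9 and 6 without peritumour 1 to 5, and 73, 78 and 7 without tumour 2, 3 and 4.

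Genes of cell division lay higher in the tumours as a group, 42 of 44 measured members by any amount, with a median of 0.71 (adjusted p = 1.2e-23; adjusted p = 0.0926 with an estimated correlation). No member passed over all genes, and 32 rose and 0 fell adjusted over the list alone, among them Cdk1 (2.06 ± 0.42), Cdc20 (2.04 ± 0.41) and Pbk (1.66 ± 0.33), whose peritumour mean of 4.30 is not shown to be above background. Fetal liver and liver tumour markers shifted up by a median of 0.82 (adjusted p = 2.84e-10; adjusted p = 0.0880 with an estimated correlation), with 3 of 37 rising over all genes (Afp, Bex1 and Prom1) and 15 adjusted over the list alone, Sox4 at 0.87 ± 0.17 among the members short of the threshold over all genes. DNA replication genes shifted up by 0.33 (adjusted p = 1.02e-07; adjusted p = 0.0903 with an estimated correlation), with 1 of 36 rising over all genes, Lig1 (0.84 ± 0.15, blocked adjusted p = 0.175), and 6 adjusted over the list alone. Glutathione and antioxidant genes shifted up by 0.24 (adjusted p = 0.000279; adjusted p = 0.461 with an estimated correlation). Of 35 members 2 rose over all genes, Cbr3 and Nqo1, and 4 adjusted over the list alone; Gpx4 read 0.55 ± 0.12 and Srxn1 1.19 ± 0.29.

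Of the lists of hepatocyte function 6 shifted down, while gluconeogenesis, fatty acid oxidation, cholesterol synthesis and the respiratory chain did not pass (adjusted p = 0.0957, 0.466, 0.604 and 0.0893). The median was -0.44 for urea cycle and amino acid catabolism (adjusted p = 1.9e-05; adjusted p = 0.168 with an estimated correlation), where Fah read -0.46, Gldc -1.14 and Cps1 -0.88 and 0 of 33 members passed in either adjustment. Secretory proteins and hepatocyte identity had a median of -0.18 (adjusted p = 1.99e-05; adjusted p = 0.168 with an estimated correlation), with 1 of 39 falling over all genes, F7, and 2 adjusted over the list alone, and plasminogen (Plg) at -0.48 ± 0.12. Cytochromes P450 and conjugation had a median of -0.51 (adjusted p = 4.62e-05; adjusted p = 0.461 with an estimated correlation), with 0 of 37 passing in either adjustment and Cyp3a25 at -1.17 and Cyp2d22 at -0.80. Methionine and one-carbon metabolism had a median of -0.26 (adjusted p = 0.00940; adjusted p = 0.168 with an estimated correlation). None of its 29 members passed over all genes, while 1 rose and 2 fell adjusted over the list alone, and Dmgdh read -1.25, Sardh -0.95 and Mthfd2 0.52. Bile acid synthesis and transport had a median of -0.29 (adjusted p = 0.00324; adjusted p = 0.511 with an estimated correlation), with 0 of 27 falling over all genes, 1 adjusted over the list alone, Baat at -1.02 and Slc27a5 at -0.68. The acute phase response had a median of -0.45 (adjusted p = 1.2e-06; adjusted p = 0.461 with an estimated correlation), with 0 of 28 passing in either adjustment, Orm3 at -1.83 and Hamp, the gene of the iron hormone hepcidin, at -1.32.

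Of the markers of other cell types, cholangiocyte and progenitor markers shifted up by a median of 0.37 (adjusted p = 0.0200; adjusted p = 0.689 with an estimated correlation), with 1 of 20 rising in either adjustment, Prom1, and Tspan8 at 2.64 ± 0.84. That list scored 1.74 on tumour 3 against -0.20 to 0.33 on the other tumours, and without tumour 3 its median was 0.01 (adjusted p = 0.889). The call was also lost without peritumour 3 (0.26, adjusted p = 0.0547) and with dim genes left out (0.14, adjusted p = 0.228). The glutathione call was lost without peritumour 2 (0.11, adjusted p = 0.0525) and the bile acid call without tumour 5 (-0.10, adjusted p = 0.190). The bile acid call was also lost without peritumour 2, tumour 2, tumour 5 and wild type 4 together (0.01, adjusted p = 0.404), the 4 arrays that stand apart, an omission chosen after the data were seen. Endothelial markers moved apart, with Emcn rising and Ehd3 falling over all genes, 5 rising and 4 falling adjusted over the list alone, and Esam at 1.20 ± 0.23; the list as a whole had an adjusted p of 0.969. With the block the macrophage (adjusted p = 0.0386), B cell (0.0266), neutrophil (0.00417) and male-biased (0.0386) lists passed too, all lower in tumours. Without the block and with an estimated correlation their adjusted p was 0.851, 0.551, 0.851 and 0.851.

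Other medians moved with the call kept. Without tumour 2, tumour 4 and peritumour 3 the glutathione median was 0.50, 0.15 and 0.38, and without tumour 1 and 4 the bile acid median was -0.51 and -0.45. It was -0.27 for cytochromes P450 without tumour 5, -0.28 for secretory proteins without tumour 2, and -0.70 and -0.28 for the acute phase without peritumour 3 and 5. It was 0.57 and 0.60 for cholangiocytes without tumour 5 and peritumour 2, and 1.86 for cell division with dim genes left out. Without the 4 arrays that stand apart it was 0.48 for glutathione, -0.25 for cytochromes P450 and 0.75 for cholangiocytes. Calls were gained for matrix and stellate markers without tumour 2 and 5 (adjusted p = 0.0313 and 0.00654), for macrophages without tumour 3 and peritumour 3 (0.00903 and 0.00304), and for acinar markers without tumour 3 (0.0244). With all arrays and an estimated correlation their adjusted p was 0.898, 0.851 and 0.851. Without peritumour 2 they were gained for cholesterol (adjusted p = 0.00137), interferon (0.0208) and male-biased genes (0.0168), against 0.952, 0.952 and 0.851 with all arrays and an estimated correlation.

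In all 11 of 32 lists shifted, 5 up and 6 down, and 0 with an estimated correlation. Other groupings of the same 10 arrays gave as many shifted lists in 65 of 100 cases, the real one included, so the number of lists does not set tumour apart from peritumour.

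**Figure D2:**
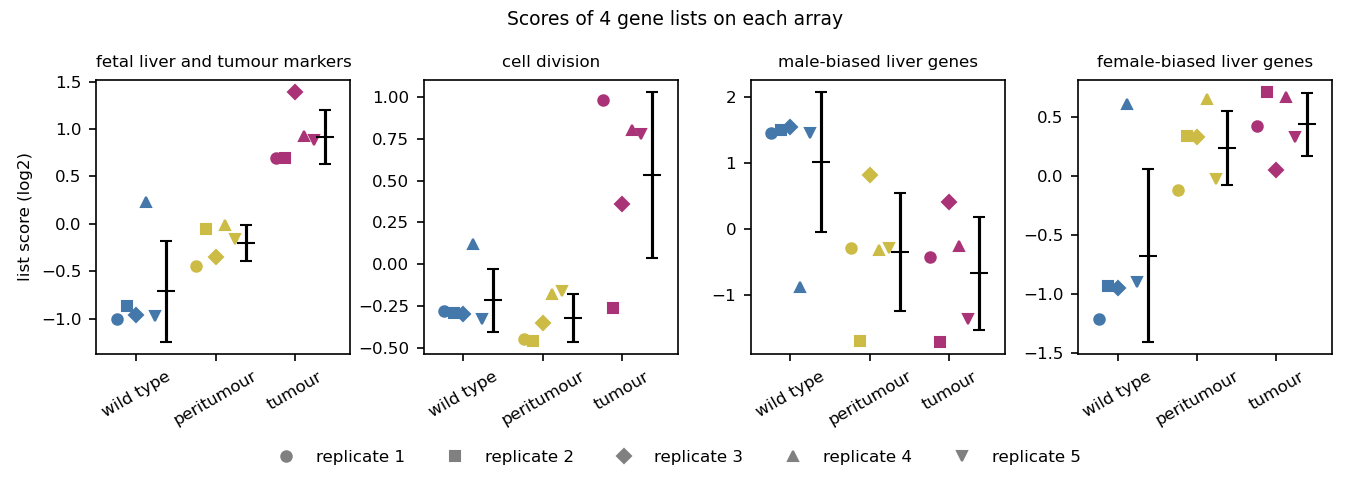
Scores of 4 gene lists on each of the 15 arrays, the score being the mean over the list's genes of the log2 difference from the gene's mean over all arrays, with 1 panel per list and its own vertical axis; symbols mark the replicate number, and the black dash and bar give the mean and SD of 5 arrays. Wild type 4 scores -0.88 for male-biased genes against 1.45 to 1.54 on the other wild type arrays, and tumour 2 scores -0.26 for cell division against 0.36 to 0.98 on the other tumours.

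The second comparison, peritumour against wild type liver, addresses how liver of deficient mice differs before the tumour itself is considered, with strain differing too. Mat1a (-3.01 ± 0.52 log2 units, SE, n = 5 and 5 arrays) fell, and Afp rose by 2.80 ± 0.42. Nqo1, a quinone reductase of the antioxidant response, rose by 1.42 ± 0.21, Parp16 by 2.75 ± 0.38, the copper chaperone gene Atox1 by 1.01 ± 0.17 and the ribosomal protein gene Rps6 by 0.96 ± 0.14, and Ankrd33b rose too. Genes that fell were Bcl7c (-2.18 ± 0.21), the transcription factor gene Nfia (-1.51 ± 0.26), the collagen gene Col5a3 (-1.36 ± 0.22), Oxsm (-0.84 ± 0.14) and Ttc27 (-0.54 ± 0.09). In each of these 12 genes the groups did not overlap, which the naming rule required, so it adds no support. The wild type means of Afp (3.78) and Ankrd33b (4.54) lay below 4.64, the highest Xist value on any array, and are not shown to be above background, so the size of these rises is uncertain.

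In limma 13 genes changed, 7 higher and 6 lower, and 10 changed at least 2-fold, 6 higher and 4 lower. Adjusted p was 0.000447 for Bcl7c and lay between 0.0197 for Parp16 and 0.0486 for Ttc27 for the others named. The groups of 361 genes (2.9%) did not overlap, where chance gives 0.79%. With the number as a block 1 gene passed, Afp (blocked adjusted p = 0.00114), and the blocked adjusted p of the other genes named above lay between 0.138 for Nqo1 and 0.210 for Rps6 and Ttc27. This fit, too, held only the 2 groups compared. The 13 genes became 1, 2 and 3 without peritumour 1, 4 and 5, 3, 3, 2 and 3 without wild type 1, 2, 3 and 5, and 63 without wild type 4. More of the called genes were lower than higher with array weights (442 higher and 881 lower), with the mean of all probe sets (33.3% higher against 53.8%), without peritumour 1 and 5 (0% and 33.3%) and without wild type 2 (33.3%). The 10 genes changed at least 2-fold became 1, 2 and 3 without peritumour 1, 4 and 5, 3, 2, 2 and 3 without wild type 1, 2, 3 and 5, and 43 without wild type 4.

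Genes with higher expression in male than in female liver lay lower in peritumour liver, 15 of 19 by any amount, with a median of -0.62 (adjusted p = 0.000588; adjusted p = 0.668 with an estimated correlation). None passed over all genes and 5 fell adjusted over the list alone, with Hsd3b5 at -5.72 ± 1.13, the transporter gene Slco1a1 at -4.92 ± 0.97 and complement gene C6 at -1.87 ± 0.49. The peritumour means of Hsd3b5 (3.88) and Slco1a1 (4.38) are not shown to be above background, so the size of these falls is uncertain. Female-biased genes lay higher, 17 of 21, with a median of 0.66 (adjusted p = 0.000172; adjusted p = 0.668 with an estimated correlation). None passed over all genes and 1 rose adjusted over the list alone, with Sult1e1 at 4.68 ± 1.03. Wild type 4 did not share the wild type levels of these genes, reading 3.68 for Hsd3b5 against 10.51 to 11.37 on the other wild type arrays. Peritumour 3 scored 0.82 for male-biased genes, against -1.69 to -0.28 on the other peritumour arrays. Eif2s3y read 7.46 to 8.30 on peritumour and 7.75 to 8.32 on wild type arrays, and the difference was -0.26 ± 0.43 (adjusted p = 0.843). Uty, Kdm5d and the female-specific transcript Xist differed by 0.01, -0.01 and -0.37.

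Acute phase genes shifted up by a median of 0.50 (adjusted p = 4.08e-06; adjusted p = 0.668 with an estimated correlation), with 0 of 28 passing in either adjustment and the metallothionein genes Mt2 and Mt1 at 4.10 ± 1.23 and 3.27 ± 1.04. Fetal liver and tumour markers shifted up by 0.26 (adjusted p = 0.000588; adjusted p = 0.668 with an estimated correlation), with 1 of 37 rising in either adjustment, Afp, and Lcn2 at 2.66 ± 0.91. The interferon response shifted up by 0.23 (adjusted p = 0.00956; adjusted p = 0.808 with an estimated correlation), with 0 of 29 passing over all genes, 1 rising adjusted over the list alone and Usp18 at 1.49 ± 0.38. Stress response genes, which include targets of amino acid shortage, had a median of 0.01 and passed as shifted up (adjusted p = 0.0387; adjusted p = 0.808 with an estimated correlation). Of its 28 members 0 passed over all genes and 2 rose and 1 fell adjusted over the list alone, with Asns at 1.93 ± 0.38 and Chac1 at 1.39 ± 0.27. The glutathione list passed as shifted up with a mean of 0.17 and a median of -0.04 (adjusted p = 0.0430; adjusted p = 0.808 with an estimated correlation), with 1 of 35 rising in either adjustment, Nqo1, and Gsta2 at 1.71 ± 0.53. Cholesterol synthesis genes lay lower in 19 of 19 members with a median of -0.72 (adjusted p = 0.0430; adjusted p = 0.879 with an estimated correlation), 0 passing in either adjustment, and Dhcr7 at -0.81 and Stard4 at -0.65. That list scored -2.20 on peritumour 2, and without this array the median was -0.15 with the test turned upward (adjusted p = 0.915).

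Markers of macrophages and Kupffer cells shifted up by a median of 0.20 (adjusted p = 0.00529; adjusted p = 0.808 with an estimated correlation), Mpeg1 reading 0.83 and Ctss 0.82. Extracellular matrix and stellate cell markers shifted up by 0.16 (adjusted p = 0.0181; adjusted p = 0.879 with an estimated correlation), with Pdgfra at 1.18. Endothelial markers shifted down with a median of -0.16 (adjusted p = 0.0102; adjusted p = 0.668 with an estimated correlation), with Nos3 at -0.56. T and NK cell markers shifted down with a median of -0.11 (adjusted p = 0.0430; adjusted p = 0.668 with an estimated correlation). Pancreatic acinar markers shifted down with a median of -0.16 (adjusted p = 0.0365; adjusted p = 0.808 with an estimated correlation), with Spink1 at 3.37 ± 1.06. The peritumour means of Thy1, Wnt2, Il2rb and Cpa1, members of the last 4 lists with small p, lay under 4.64 and are not shown to be above background, so their differences are left out. No member of these 5 lists passed over all genes, and adjusted over the list alone 3 endothelial genes and 1 T and NK cell gene fell. Neutrophil markers scored 2.75 on wild type 4 against -0.87 to -0.35 on the other wild type arrays.

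In all 13 of 32 lists shifted, 8 up and 5 down, and 0 with an estimated correlation. Without peritumour 4 the number was 8, and other groupings of the 10 arrays gave as many in 47 of 100 cases. The calls for the male-biased, female-biased, acute phase and fetal marker lists held without any 1 array, and each of the other 9 was lost without at least 1 array. Holding in this way does not set the 4 lists apart from other groupings of the arrays. Those gave a p as small in 15, 18, 24 and 18 of 100 cases, the real one included, in a check chosen after the result was seen. The glutathione call was lost without peritumour 1, 3 and 4 and wild type 4 (adjusted p = 0.110, 0.274, 0.152 and 0.107, medians -0.05, -0.07, -0.08 and -0.01), with quantile normalization (0.152) and with dim genes left out (0.312). The cholesterol call was lost without peritumour 2, 3 and 5 and wild type 4 and 5 (adjusted p = 0.915, 0.0846, 0.0822, 0.184 and 0.0676, medians -0.15, -0.76, -0.73, -0.66 and -0.72) and with the mean of all probe sets (0.102). The stress response call was lost without peritumour 1, 4 and 5 and wild type 1, 4 and 5 (adjusted p = 0.136, 0.208, 0.247, 0.111, 0.138 and 0.0550, medians -0.06, -0.06, -0.09, -0.03, -0.05 and 0.01), with quantile normalization (0.193) and with dim genes left out (0.379). For interferon it was lost without peritumour 1 and 5 (adjusted p = 0.110 and 0.103, medians 0.14 and 0.11) and with dim genes left out (0.137), and for matrix without peritumour 2 and 4 and wild type 1 (adjusted p = 0.0829, 0.0549 and 0.0580, medians 0.10, 0.10 and 0.13). For macrophages it was lost without peritumour 2 and wild type 5 (adjusted p = 0.0986 and 0.254, medians 0.17 and 0.03), and for endothelial markers without peritumour 3 and wild type 4 (0.130 and 0.167). For T and NK cells it was lost without peritumour 1, 3 and 4 and wild type 4 (adjusted p = 0.133, 0.0846, 0.0796 and 0.167, medians -0.07, -0.10, -0.11 and -0.08) and with quantile normalization (0.550). For acinar markers it was lost without peritumour 4 and 5 and wild type 1 and 5 (adjusted p = 0.0796, 0.0645, 0.0580 and 0.0606) and with quantile normalization (0.198). Of the omissions chosen after the data were seen, leaving out peritumour 2 with tumour 2 ended the calls for cholesterol (adjusted p = 0.662), matrix (0.0970) and macrophages (0.111). Leaving out the 4 arrays that stand apart ended those for cholesterol (median -0.07, adjusted p = 0.999), T and NK cells (0.136) and endothelial markers (0.136).

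Other medians moved with the call kept. The fetal marker median was 0.41, 0.16 and 0.14 without peritumour 1, 2 and 4 and 0.12, 0.13, 0.46 and 0.15 without wild type 1, 3, 4 and 5, and 0.16 and 0.59 with the mean of all probe sets and with dim genes left out. The acute phase median was 0.24 and 0.20 without peritumour 5 and wild type 5, and the interferon median 0.42, 0.14 and 0.15 without peritumour 2 and wild type 3 and 5. The macrophage median was 0.11 and 0.53 without wild type 3 and 4, the matrix median 0.28 without wild type 4 and the female-biased median 0.35 without wild type 1. The glutathione median was 0.18 and 0.01 without peritumour 2 and 5, and the stress median 0.17, 0.15, 0.04 and 0.10 without peritumour 2 and 3 and wild type 2 and 3. The male-biased median was -1.36 with dim genes left out. Without peritumour 2 and tumour 2 the medians were 0.18 for glutathione, 0.16 for fetal markers, 0.17 for the stress response and 0.42 for interferon. Without the 4 arrays that stand apart they were 0.15 for glutathione, 0.15 for the stress response, 0.50 for interferon, 0.42 for macrophages and -0.26 for acinar markers. For the extracellular matrix the median was 0.09 with the mean of all probe sets and 0.29 with dim genes left out, and for macrophages 0.40 with dim genes left out. Calls were gained for cytochromes P450 without peritumour 2 (adjusted p = 0.00660), and for adipocyte and blood markers without wild type 2 and 4 (0.0391 and 0.0397) and with the mean of all probe sets (0.0295), against 0.879 and 0.668 with all arrays and an estimated correlation.

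The third comparison, tumour against wild type liver, spans both steps and again carries the strain difference. Afp rose by 6.54 ± 0.42 log2 units (SE, n = 5 and 5 arrays), Bex1 by 5.18 ± 0.78, the prohormone-processing enzyme gene Cpe by 4.84 ± 0.97, Ly6d by 3.91 ± 0.69 and Nupr1 by 3.89 ± 0.39. Genes that fell were Mat1a (-3.19 ± 0.52), Eif2s3y (-2.73 ± 0.43), Nfia (-2.53 ± 0.26), Gdf10 (-2.23 ± 0.26) and Bcl7c (-2.17 ± 0.21). Psat1 rose by 3.54 ± 0.27 and Asns, the asparagine synthetase gene, by 1.90 ± 0.38. In each of these 12 genes all tumour values lay on one side of all wild type values. The naming rule required this of all but Psat1 and Asns, so for the others it adds no support. The wild type means of Afp and Psat1 (3.78 each) and Bex1 (3.53) and the tumour mean of Gdf10 (4.23) lay below 4.64, the highest Xist value on any array, and are not shown to be above background, so the size of these changes is uncertain. Of the genes named below, the same holds for Birc5, Pbk, Prom1 and Elovl7 in wild type liver, Hsd3b5 in tumours and Uty in both. Cpe read 7.44 on wild type 4 but 3.59 to 4.48 on the other wild type arrays, so the size of its rise is uncertain too.

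In limma 300 genes changed, 171 higher and 129 lower, and 140 changed at least 2-fold, 100 higher and 40 lower. Adjusted p was 2.82e-06 for Afp, 1.15e-05 for Psat1, 0.00537 for Bex1, 0.0204 for Cpe and Asns, 0.0123 for Ly6d, 0.00746 for Mat1a and 0.00720 for Eif2s3y. It was 0.000154 for Nupr1 and Nfia, 0.000701 for Gdf10 and 0.000115 for Bcl7c. The groups of 645 genes (5.2%) did not overlap, where chance gives 0.79%. A fit of only the 2 groups without the block gave 55 genes. With the number as a block in such a fit 11 genes passed, 10 of them among the 300. These included Afp, Psat1, Nfia and Bcl7c (blocked adjusted p = 0.00836 each), Nqo1 (0.0111), Nupr1 (0.0114), Cbr3 (0.0151) and Bex1 (0.0239), and for all other genes named as changed in this comparison it lay between 0.0970 for Mat1a and Gdf10 and 0.214 for Slco1a1. The 300 genes became 199 and 162 without tumour 1 and 4, and 79, 83, 96, 665 and 84 without wild type 1 to 5. With array weights 989 were higher and 1044 lower, and without the 4 arrays that stand apart 1011 and 1026. The 140 genes changed at least 2-fold became 53, 55, 55, 290 and 56 without wild type 1 to 5.

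Fetal liver and tumour markers shifted up by a median of 1.20 (adjusted p = 3.56e-15), with 10 of 37 rising over all genes and 20 rising and 1 falling adjusted over the list alone. This list also passed with an estimated correlation (adjusted p = 0.0200). Cell division shifted up by 0.50 (adjusted p = 1.04e-15; adjusted p = 0.205 with an estimated correlation), with 6 of 44 rising over all genes, among them Birc5 (2.24 ± 0.46), Cdk1 (2.01 ± 0.42) and Pbk (1.63 ± 0.33), and 26 adjusted over the list alone. DNA replication shifted up by 0.38 (adjusted p = 2.48e-07; adjusted p = 0.107 with an estimated correlation), with 5 of 36 rising over all genes, among them Rrm2 (2.58 ± 0.58) and Lig1 (0.94 ± 0.15), and 10 rising and 1 falling adjusted over the list alone. Glutathione genes shifted up by 0.39 (adjusted p = 1.56e-05; adjusted p = 0.307 with an estimated correlation), with 5 of 35 rising over all genes, among them Cbr3 (3.62 ± 0.37) and Nqo1 (2.61 ± 0.21), and 6 adjusted over the list alone.

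Male-biased genes shifted down with a median of -1.44 (adjusted p = 5.88e-05; adjusted p = 0.314 with an estimated correlation), with 2 of 19 falling over all genes, Hsd3b5 (-5.73 ± 1.13) and Slco1a1 (-4.40 ± 0.97), and 9 adjusted over the list alone. For Hsd3b5 1 of 5 tumours lay below all wild type arrays, of which wild type 4 read 3.68. Female-biased genes shifted up by 0.81 (adjusted p = 1.56e-05; adjusted p = 0.205 with an estimated correlation), with 2 of 21 rising over all genes, Hao2 (3.07 ± 0.60) and Prom1 (3.05 ± 0.46), and 5 adjusted over the list alone. Secretory proteins and hepatocyte identity shifted down with a median of -0.25 (adjusted p = 0.000162; adjusted p = 0.303 with an estimated correlation), with 2 of 39 falling over all genes, complement gene C9 (-2.12 ± 0.36) and F7 (-1.03 ± 0.16), and 7 adjusted over the list alone. Methionine and one-carbon metabolism shifted down with a median of -0.34 (adjusted p = 0.0411, and adjusted p = 0.307 with an estimated correlation). Of its members 2 of 29 fell over all genes, Mat1a and Cbs (-0.95 ± 0.21), and 1 rose and 3 fell adjusted over the list alone. Mat1a is the gene these mice lack, so its fall comes with the design and is no evidence about the pathway. A list value without Mat1a is not given here. Bile acid genes shifted down with a median of -0.59 (adjusted p = 0.0220; adjusted p = 0.574 with an estimated correlation), with 2 of 27 falling over all genes, Baat (-1.18 ± 0.23) and Slco1a1, and 5 adjusted over the list alone. Urea cycle genes shifted down with a median of -0.46 (adjusted p = 0.0153; adjusted p = 0.413 with an estimated correlation), with 0 of 33 falling over all genes and 2 adjusted over the list alone. Cholesterol synthesis shifted down with a median of -0.65 (adjusted p = 0.0395; adjusted p = 0.705 with an estimated correlation), with 0 of 19 passing in either adjustment.

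Of other cell types, matrix and stellate markers shifted up by 0.44 (adjusted p = 0.00154; adjusted p = 0.637 with an estimated correlation) and cholangiocyte markers by 0.38 (adjusted p = 0.00905; adjusted p = 0.551 with an estimated correlation). Over all genes 0 of 37 and 1 of 20 members rose, and adjusted over the list alone 2 rose and 2 fell of the former and 3 rose of the latter. Without tumour 3 the medians were 0.09 (adjusted p = 0.392) and 0.14 (adjusted p = 0.405). Adipocyte, mesothelium and blood markers shifted down with a median of -0.19 (adjusted p = 0.0351; adjusted p = 0.307 with an estimated correlation), with 0 of 11 passing in either adjustment. Within lists that did not pass, the lipid genes Fabp4 (3.25 ± 0.52), Scd2 (3.04 ± 0.66) and Elovl7 (2.34 ± 0.48), the stress gene Atf3 (1.87 ± 0.39) and the endothelial gene Emcn (1.67 ± 0.28) rose, and Ehd3 (-1.39 ± 0.18) and Uty (-0.49 ± 0.11) fell over all genes. Fatty acid and triglyceride synthesis held 5 risen and 1 fallen gene of 36, stress response 5 risen of 28 and endothelial markers 2 risen and 4 fallen of 28. Adjusted over the list alone these were 6 and 4, 6 and 2, and 3 and 11.

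In all 14 of 32 lists shifted, 7 up and 7 down, and 1 with an estimated correlation. Without wild type 5 the number was 9, and other groupings of the 10 arrays gave as many in 42 of 100 cases. The methionine call was lost without tumour 2, 4 and 5 and wild type 5 (adjusted p = 0.0550, 0.0537, 0.0681 and 0.0753) and with the mean of all probe sets (0.0741). The bile acid call was lost without tumour 5 (median -0.37, adjusted p = 0.325) and wild type 5 (-0.53, adjusted p = 0.0637), and the urea cycle call without tumour 4 and wild type 5 (0.0537 and 0.0728). The cholesterol call was lost without tumour 2 (median -0.28, adjusted p = 0.540), and without tumour 3 and wild type 4 and 5 (adjusted p = 0.0870, 0.119 and 0.0601). Adipocyte and blood markers lost theirs without tumour 3 and wild type 5 (adjusted p = 0.0823 and 0.0601) and with quantile normalization (0.0725), and cholangiocytes with dim genes left out (median 0.85, adjusted p = 0.116) besides tumour 3. Of the omissions chosen after the data were seen, leaving out peritumour 2 with tumour 2 ended the cholesterol call (median -0.28, adjusted p = 0.228). Leaving out the 4 arrays that stand apart ended the calls for cholesterol (median -0.30, adjusted p = 0.221) and bile acids (median -0.20, adjusted p = 0.317).

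With the call kept, the glutathione median was 0.14, 0.20 and 0.25 without tumour 1 and 4 and wild type 5, and the female-biased median 0.50 without wild type 1. With dim genes left out the medians were 2.26 for fetal markers, 1.35 for cell division and 0.65 for DNA replication. Without the 4 arrays that stand apart they were 0.72 for glutathione, -0.73 for the urea cycle, 0.74 for matrix, 0.83 for cholangiocytes and 1.30 for female-biased genes. The call for cytochromes P450 was gained without tumour 1, 3 and 4 (adjusted p = 0.00708, 0.0183 and 0.0254), without wild type 1, 2 and 3 (0.0416, 0.0413 and 0.0347), with quantile normalization (0.0495), with dim genes left out (0.0104) and with the block (0.0463). With all arrays and an estimated correlation its adjusted p was 0.669. For interferon it was gained without tumour 1 and 2 and wild type 2 and 4 (adjusted p = 0.0437, 0.00287, 0.0337 and 0.00513), and for macrophages without wild type 4 (0.00980), against 0.669 and 0.822 with all arrays and an estimated correlation. For T and NK cells it was gained without tumour 4 and 5 and wild type 1 and 3 (adjusted p = 0.0287, 0.0485, 0.0436 and 0.0220) and with the mean of all probe sets (0.0335), against 0.413 with an estimated correlation. The stress response gained it without tumour 1 and 3 and wild type 2 and 3 (adjusted p = 0.0407, 0.0475, 0.0416 and 0.0212), against 0.637 with an estimated correlation. Endothelial markers gained it without tumour 3 and wild type 1 and 3 (adjusted p = 0.0147, 0.0389 and 0.0281), with quantile normalization (0.0446) and with dim genes left out (0.00261), against 0.584 with an estimated correlation.

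The labels order the tissues from wild type through peritumour to tumour, and 2 genes changed in both steps, both upward each time. Nqo1 rose by 1.42 and then by 1.19 (blocked adjusted p = 0.138 and 0.146), and Afp by 2.80, from a wild type level not shown to be above background, and then by 3.73. Independent lists of these sizes would share 0.0273 genes. Unchanged groups sharing the peritumour arrays gave a median of 0 in 50 simulations. Groups without change leave almost no called genes in either step, so that 0 was set in advance and is not read as evidence about the 2 genes. With the peritumour arrays split between the steps, 0 genes passed in both in all 20 splits. A split leaves fewer arrays per step, and leaving out 1 array already gave as few as 1 and 6 called genes in the 2 steps. This 0 was therefore also nearly set in advance and is not read as evidence against the 2 genes. The count was 1 with the mean of all probe sets. It was 65 without the 4 arrays that stand apart, an omission chosen after the data were seen. Across genes the log2 changes of the steps correlated at -0.115 with a covariance of -0.015, against -0.503 and -0.040 simulated with no effect; genes are not independent replicates. The simulated groups were independent, while same-numbered peritumour and tumour arrays deviated together, which by itself makes both values less negative, so the gap from the simulation is not read as shared change.

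The sex chromosome and strain-linked genes were read in every comparison. Kdm5d differed by -1.01 between tumour and peritumour and by -1.02 between tumour and wild type (adjusted p = 0.157 and 0.0847), Uty by -0.51 between tumour and peritumour (0.0693), and Xist by 0.13 and -0.24. The means of Kdm5d, Uty and Xist lay under 4.64 in all 3 groups and are not shown to be above background, so the size of these differences is uncertain. Nnt, which carries a deletion in C57BL/6J and whose probe set's place relative to it is not given in the sources used here, read highest in the C57BL/6J group. It gave 9.17 ± 0.09 (SD, n = 5) in wild type, 8.64 ± 0.59 in peritumour and 8.54 ± 0.41 in tumour, with differences that did not pass (adjusted p = 0.933, 0.457 and 0.176 for tumour against peritumour, peritumour against wild type and tumour against wild type).

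The 4 measured sex chromosome genes had medians of -0.76 in tumour against peritumour, -0.14 in peritumour against wild type and -0.76 in tumour against wild type, with 1, 0 and 2 falling over all genes and 3, 0 and 3 adjusted over the list alone. The 2 measured genes with loss-of-function alleles that differ between the strains had medians of -0.04, 0.10 and 0.06, with 0 passing over all genes and 0, 0 and 1 falling adjusted over the list alone, and both lists were too short for a list test.

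With all arrays, the values as deposited and no block, the lists that passed in no comparison were glycolysis, gluconeogenesis and glycogen, fatty acid oxidation, fatty acid synthesis, the respiratory chain, beta-catenin targets, ERK targets, p53 targets, B cells and neutrophils. For tumour against peritumour their medians were 0.18, -0.19, -0.07, 0.13, 0.14, 0.14, 0.03, 0.09, -0.12 and -0.35. For tumour against wild type they were 0.09, -0.31, -0.26, -0.22, 0.02, -0.01, 0.09, 0.21, -0.24 and -0.34.

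All 10 passed in at least 1 comparison under some alternative with the preset correlation. For tumour against peritumour and with adjusted p in parentheses, the beta-catenin median was 0.51 (0.0194) without tumour 5. Glycolysis read 0.11 (0.0368) without tumour 5, and ERK targets 0.21 (0.0220) without peritumour 2. The respiratory chain read 0.16 (0.00503) with quantile normalization, 0.14 (0.0495) with dim genes left out, and 0.18 (0.00585), 0.17 (0.0105) and 0.18 (0.00175) without tumour 2, tumour 4 and peritumour 3. Gluconeogenesis read -0.30 (0.0476) without tumour 3 and -0.43 (0.0120) without peritumour 2, and fatty acid oxidation -0.19 (0.0397) without tumour 1 and -0.26 (0.0120) without peritumour 2. B cell markers read -0.16 (0.0258) with quantile normalization, -0.15 (0.0362) without tumour 4, and -0.15 (0.0247), -0.15 (0.0203) and -0.12 (0.0418) without peritumour 1, 3 and 5. For peritumour against wild type, neutrophil markers read 0.40 (0.000525) without wild type 4. With all arrays and an estimated correlation, adjusted p for tumour against peritumour was 0.952, 0.461, 0.851 and 0.867 for the first 4 of these lists and 0.468, 0.952 and 0.551 for gluconeogenesis, fatty acid oxidation and B cells, and 0.973 for neutrophils in peritumour against wild type.

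For tumour against wild type and with adjusted p in parentheses, the beta-catenin median was 0.41 (0.0476) without tumour 2 and 0.52 (0.0175) without tumour 5. Glycolysis read 0.16 (0.0331), 0.16 (0.0262), 0.13 (0.0413) and 0.11 (0.0308) without tumour 2, tumour 5, wild type 2 and wild type 4. The respiratory chain read 0.09 (0.0288) without tumour 2 and 0.07 (0.0492) without tumour 4, and fatty acid oxidation -0.40 (0.0170) without tumour 1. The p53 targets read 0.26 (0.0488) with the mean of all probe sets, 0.21 (0.0236) with the block, and 0.17 (0.0437), 0.21 (0.0436), 0.25 (0.0416) and 0.20 (0.0366) without tumour 1, tumour 4, wild type 1 and wild type 3. B cell markers read -0.20 (0.0492), -0.27 (0.0416) and -0.26 (0.0201) without tumour 4, wild type 2 and wild type 3. With all arrays and an estimated correlation, adjusted p was 0.822, 0.307 and 0.815 for beta-catenin targets, glycolysis and the respiratory chain, and 0.815, 0.314 and 0.551 for fatty acid oxidation, p53 targets and B cells.

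The omissions chosen after the data were seen gave the following medians, with adjusted p in parentheses. Without the 4 arrays that stand apart the beta-catenin median was 1.09 (9.17e-06) in tumour against peritumour and 1.11 (2.85e-05) in tumour against wild type. Glycolysis read 0.28 (0.00240) and 0.23 (0.00148), fatty acid synthesis 0.33 (0.00240) and 0.24 (0.0180), and ERK targets 0.16 (0.0173) in tumour against peritumour. Without peritumour 2 and tumour 2, tumour against peritumour gave 0.13 (0.0340) for glycolysis, -0.41 (0.00825) for gluconeogenesis and 0.22 (0.0486) for ERK targets, and tumour against wild type gave 0.16 (0.0196) for glycolysis and 0.09 (0.0200) for the respiratory chain. Of lists that had passed in another comparison, matrix markers in tumour against peritumour read 0.50 (0.00825) without these 2 arrays and 0.62 (7.96e-06) without the 4, and interferon genes in tumour against wild type 0.37 (0.00279) and 0.37 (0.00102). Without the 4 arrays macrophage markers read 0.56 (0.000417) in tumour against wild type and DNA replication 0.06 (0.0393) in peritumour against wild type, where cytochromes P450 read 0.16 (0.0101) without peritumour 2 and tumour 2. With all arrays and an estimated correlation, adjusted p was 0.952 and 0.815 for fatty acid synthesis in tumour against peritumour and tumour against wild type, and 0.879 for DNA replication in peritumour against wild type, and the other lists of this paragraph have theirs above.

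**Figure D3:**
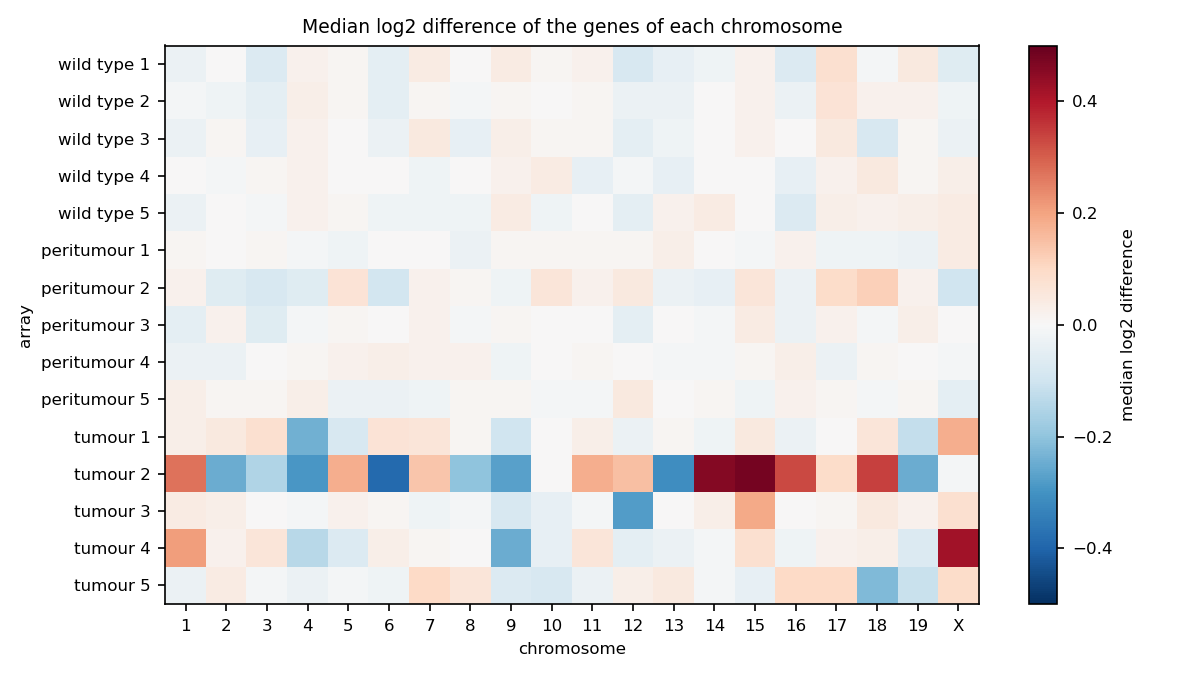
Median log2 difference of the genes on each chromosome (columns) on each array (lines) from the mean of peritumour 1, 3, 4 and 5 (the array itself left out), after subtracting the array's median over all 6321 genes used; the colour bar gives the scale in log2 units. Tumour 2 ranges from -0.39 on chromosome 6 to 0.48 on chromosome 15, and tumour 4 reads 0.42 on chromosome X.

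Genes of single chromosomes lay together above or below the rest on several tumour arrays. Among 6321 genes with a mean above 6, the SD of the chromosome medians was 0.275 on tumour 2, 0.132 on tumour 4, 0.089 on tumour 1, 0.084 on tumour 3 and 0.080 on tumour 5, against 0.019 to 0.061 on peritumour and 0.025 to 0.045 on wild type arrays. With genes shuffled over chromosomes, the largest absolute median stayed within 0.08, 0.17, 0.07, 0.08 and 0.21 on tumours 1 to 5 in 95% of 1000 shuffles, and 5, 14, 4, 4 and 1 chromosomes lay beyond it. On tumour 5 that was chromosome 18 at -0.22, just beyond the limit. On the other arrays 2 chromosomes lay beyond it on wild type 1 and 0 elsewhere. Chromosome 12 read -0.28 on tumour 3, chromosome 9 -0.25 on tumour 4 and chromosome 4 -0.24 on tumour 1. Eif2s3y read 4.56, 5.66, 7.04, 4.62 and 4.02 on tumours 1 to 5.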

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

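Chosen only after the result was seen were the tests of degraded RNA, wild type RNA, a shared state, uneven signal, female tissue, female animals, arrays that stand apart, strain, and all regroupings of the arrays; the tests of tumour tissue in peritumour 2 and of chromosome gain or loss were set before. A value stands out here when its gap to the nearest of the other 4 arrays is over 0.71 of the group's range, which chance gives in about 1 of 20 groups. Of 315 groups of 5 values 52 (16.5%) held such a value, 37 of 213 for genes and 15 of 102 for lists.

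Peritumour 2 stood out for Mat1a (11.44 against 8.84 to 9.29), Bex1 (7.60), Gldc (8.17), Pdgfra (7.98), Wnt2 (3.78), Slc27a5 (12.37), Aldh1l1 (12.38), the methionine list (-0.25) and the beta-catenin list (-0.79), and it lay close to tumour 2. Degraded RNA is argued against by 0 of 4 3-prime to 5-prime differences (actin and pyruvate carboxylase) above all other arrays of the group. That of Gapdh, outside this test, was nonetheless highest in peritumour 2 (-0.05 against -0.25 to -0.07). Over 154 genes, peritumour 2 had a median position of 0.09 between peritumour (0) and tumour (1) means (interval -0.01 to 0.20, genes not being independent). Tumour 2 itself lay at 0.50 (0.35 to 0.66) on this scale, and 33.1% of the genes lay past the midpoint on peritumour 2. The median argues against peritumour 2 being wholly tumour tissue like that of tumour 2. Because tumour 2 itself lay short of 1, the test cannot exclude some tumour tissue in peritumour 2. Wild type RNA as the whole cause of its distance is argued against by a highest correlation of 0.952 with wild type arrays, against 0.969 to 0.986 for the other peritumour arrays, and by its male-biased score of -1.69, lowest of the group, but some wild type RNA in it cannot be told apart from other causes: the median share was 81.8% over 67 genes (56.9 to 90.3) against 41.6% implied by Mat1a, 86.2% over 54 genes lower in wild type and -12.6% over 13 genes higher in wild type, and 46.7% and 55.1% over 475 and 764 genes of any size. The readings disagree, the prediction fixed no direction or size, the reading was settled after the first result (-12.6) was seen, and genes picked by the other arrays tend to regress. A state shared by 1 animal may also account for it, as the deviations correlated at 0.673 against 0.104 to 0.353 in the other same-numbered pairs, and no label says whether the arrays share an animal.

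Single tumour arrays, tumour 2 above all, showed shifts of whole chromosomes. Eif2s3y was low on tumours 1, 2, 4 and 5 (4.02 to 5.66), while tumour 3 (7.04) lay little below the lowest peritumour value (7.46). Uneven signal of outlying arrays is argued against by the SD of chromosome medians in peritumour 2, which was 0.22 times that of tumour 2, and female tissue by the highest tumour Xist, -0.11 log2 units from the highest wild type value. A candidate explanation is gain or loss of chromosomes in tumour cells: 95.3% of 192 bins of 20 neighbouring genes on 14 shifted chromosomes, counted per array, went with the shift (11 of the 14 and 157 of the 192 on tumour 2, 1 and 10 on tumour 3, 2 and 25 on tumour 4, and 0 on tumours 1 and 5), against 55.2% of the same bins in peritumour 2. The settings of that test were not in its prediction; 9 settings gave 93.6 to 97.4%, and a held-out check added later gave 79 of 81 bins. It separates whole from local shifts only, was found and tested on the same data, and leaves Eif2s3y untested.

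Male-biased genes were low and female-biased genes high in Mat1a-deficient liver against wild type. Neither list passed with an estimated correlation (adjusted p = 0.668 each for peritumour, and 0.314 and 0.205 for tumour). Other groupings of the arrays gave a p as small for the male-biased and female-biased lists in 15 and 18 of 100 cases for peritumour. For tumour the numbers were 10 and 7, so chance is not excluded. Female animals are argued against by the lowest peritumour Eif2s3y, -0.30 log2 units from the lowest wild type value. For peritumour against wild type the male-biased median was -0.69 without the 4 arrays that stand apart. That omission also takes out wild type 4, which works against the difference, so it is a weak test of outlying arrays. Without only peritumour 2 and tumour 2 the median was -0.60 (adjusted p = 0.00716), which argues against peritumour 2 as the whole cause. Strain and genotype cannot be told apart, as the design holds 2 combinations of them. Wild type 4 itself scored -0.88 for male-biased genes and 0.61 for female-biased genes. Peritumour 3 and tumour 3 shared the low male-biased scores only in part, at 0.82 and 0.41 against 1.45 to 1.54 on the other wild type arrays. The other peritumour arrays scored -1.69 to -0.28 and the other tumours -1.70 to -0.26.

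Wild type 4 stood out further for Afp (4.69), Baat (9.36), Bex1 (4.26), Birc5 (4.58), Cdk1 (6.28), Col5a3 (5.57), Cpe (7.44), Elovl2 (10.05), Elovl7 (4.94), Hsd3b5 (3.68), Ly6d (9.07), Prom1 (6.39), Slco1a1 (4.40), Spink1 (9.76) and Uty (4.31). Its list scores stood out for bile acids (-0.16), fetal markers (0.23), cell division (0.12), matrix (0.32), neutrophils (2.75), cholangiocytes (0.20) and the loss-of-function alleles (1.32). Tumour 3 stood out for matrix (1.68), macrophages (0.47), cholangiocytes (1.74) and Hao2 (4.80), and tumour 2 for Rrm2 (10.18). Peritumour 1 stood out for Eif2s3y (8.30), peritumour 3 for Cxcl12 (9.47) and the urea cycle list (0.37), peritumour 4 for Nos3 (6.10) and Psat1 (5.02), and peritumour 5 for Bcl7c (5.73), Nfia (7.52) and Rps6 (7.09). Wild type 1 stood out for Atox1 (10.42), wild type 3 for Stard4 (9.53), and wild type 5 for Eif2s3y (8.32), Hao2 (5.25), Kdm5d (5.57) and Rps6 (6.97). Of the 2246 probe sets with several gene symbols or none, 7 changed in tumour against peritumour, 7 in peritumour against wild type and 64 in tumour against wild type.

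Other groupings of the arrays tested whether chance can be excluded. For tumour against peritumour 2 of 100 groupings, the real one included, gave as many as 26 genes (highest other 216) and 2 as many as 16 genes at least 2-fold (highest other 106). For peritumour against wild type the numbers were 2 for 13 genes (highest other 97) and 2 for 10 at least 2-fold (highest other 55), and for tumour against wild type 1 for 300 genes (highest other 197) and 1 for 140 (highest other 93). For the comparisons against wild type, whose arrays are not paired, these shares argue against chance alone for the counts of genes. For tumour against peritumour they cannot exclude chance, because the groupings ignore the pairs. For the first 2 comparisons the other grouping with more genes points to a structure of the samples. It joined tumour 3 to peritumour 1, 3, 4 and 5, or peritumour 3 to wild type 1, 2, 3 and 5. With the numbers taken as pairs, 13 of the groupings of tumour and peritumour part all pairs, the real one included, and the others leave some pairs together. Of these 13, 1 gave as many as 26 genes and 1 as many as 16 at least 2-fold (highest other 0 for both), and 13 are too few for a share under 0.05. For 2 genes in both steps 1 of 100 regroupings gave as many (highest other 0). Other groupings gave a median of 0 called genes in each of the first 2 comparisons, so an overlap of 0 was nearly set in advance. Chance is therefore not excluded for these 2 genes by the regroupings. For the number of shifted lists chance cannot be excluded, with 65, 47 and 42 of 100 groupings as large as 11, 13 and 14 (highest other 21, 21 and 22).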

How the results depend on the processing

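Leaving out peritumour 2 with tumour 2, or these with wild type 4 and tumour 5 (the 4 arrays that stand apart), was chosen after the data were seen, while the other alternatives were planned. For named genes under the alternatives fixed beforehand, 1926 values kept direction and side of the threshold, 362 lost a call, 98 gained one and 0 turned. For the lists the numbers were 1249, 100, 80 and 2, with direction taken from the list test and not from the median. A median could change sign without being counted as turned, as for glutathione in peritumour against wild type (-0.04, and 0.18 without peritumour 2). For tumour against peritumour, Afp and Psat1 were called in every alternative run for them. Dim signals near background limit what genes such as Kdm5d and Uty, or Afp in wild type liver, can show.

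For tumour against peritumour, the 26 genes (16 at least 2-fold) became 52 (33) with median centring, 41 with the mean of all probe sets, 4 (4) with only the 2 groups, 1087 (311) with array weights, 6 (6) with the block, 154 (78) without peritumour 2 and tumour 2, and 503 (179) without the 4 arrays. The first set was shared in 25, 22, 4, 26, 5, 26 and 26 genes. Leaving out single arrays gave 6 to 144 genes, 6 to 78 at least 2-fold and 11 to 16 lists.

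For peritumour against wild type, the 13 genes (10) became 5 (5) with quantile normalization, 6 (6) with centring, 1323 (164) with weights, 1 (1) with the block and 571 (144) without the 4 arrays. The 13 lists became 8 with dim genes left out, where lists left with fewer than 5 members were not tested. They became 12 with the block, where T and NK cells were lost (adjusted p = 0.0954). Single arrays left out gave 1 to 63 genes, 1 to 43 at least 2-fold and 8 to 14 lists.

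For tumour against wild type, the 300 genes (140) became 55 (42) with only the 2 groups, 2033 (483) with weights, 11 (11) with the block, 671 (249) without peritumour 2 and tumour 2, and 2037 (513) without the 4 arrays. Single arrays left out gave 79 to 665 genes, 53 to 290 at least 2-fold and 9 to 20 lists. With an estimated correlation the shifted lists were 0, 0 and 1 in the 3 comparisons, and the fixed block left the lists at 15, 12 and 16.

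The 2 genes changed in both steps became 1 with the mean of all probe sets, 0 with the peritumour arrays split and 65 without the 4 arrays. The 0 was nearly set in advance by the fewer arrays per step. The direction of the list test turned for the cholangiocyte list in tumour against peritumour without tumour 3 (median 0.01; range over single arrays 0.01 to 0.60) and for cholesterol synthesis in peritumour against wild type without peritumour 2 (median -0.15; range over single arrays -1.02 to -0.15). For all of these the cause was not tested, except that fewer arrays or groups leave less information on the spread.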

Other observations

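The per-list regroupings given here were chosen only after the result was seen.

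The 5 tumours differed among themselves in several gene groups. Beta-catenin targets, which include genes of the liver zone around the central vein, scored 2.02 on tumour 1, 1.52 on tumour 4, -0.16 on tumour 3, -1.39 on tumour 2 and -1.64 on tumour 5. Cell division scored 0.98, -0.26, 0.36, 0.80 and 0.78 on tumours 1 to 5, so tumour 2 lay within the range of the non-tumour arrays. Bile acid genes scored -1.39 and cytochromes P450 -1.36 on tumour 5, against -0.81 to 0.19 and -0.85 to 0.21 on the other tumours. Cholesterol synthesis scored -2.20 on peritumour 2 and -2.18 on tumour 2.

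Regrouping tumour and peritumour arrays, a p as small as the real one came up in 1 of 100 groupings for fetal markers, 2 for the urea cycle, 2 for DNA replication, 3 for cell division and 5 for methionine. It came up in 9 for the acute phase, 13 for secretory proteins, 24 for glutathione, 29 for cytochromes P450, 41 for bile acids and 61 for cholangiocytes. Among the lists shifted in peritumour against wild type the lowest were 13 for pancreatic acini and 14 for T and NK cells, with 15 for male-biased and 18 for female-biased genes. Among those shifted in tumour against wild type they were 1 for fetal markers, 2 for secretory proteins, 4 for DNA replication, 5 for adipocyte and blood markers, and 7 for cell division and female-biased genes. These are 96 tests without adjustment, of which 9 gave 5 or fewer. Each count includes the real grouping, and the groupings of tumour and peritumour arrays ignore the same-numbered pairs.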
